A study of Mus musculus with 10 samples.

How the data were processed

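Whole-genome expression was measured with oligonucleotide arrays of probe sets on total RNA from B6xBALB F2 mice, F2 animals being the grandchildren of a cross between the C57BL/6 and BALB/c inbred strains. Per the labels, 8 samples came from cystic fibrosis knockout mice, which lack the chloride channel gene Cftr, and 2 from controls. Codes in the sample titles place 5 knockouts in a group H and 3 in a group L. The labels do not spell these letters out, and the series title speaks of variable weight. Both controls carry the letter D in place of H or L, which is not spelled out either. Whatever it codes cannot be told apart from the knockout. The titles also carry the letter M or F (6 and 4 samples) and a number, which falls in a lower range (3 knockouts, both controls) or an upper range (5 knockouts). The labels name whole right lung as the source, while the series title names an intestinal phenotype. The design text gives other animal numbers than the samples analysed here; further animals were not analysed here.

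The authors deposited a linear intensity per probe set and array in a single file of the whole series. The summarization, background correction and normalization are not given in the sources used here. Array medians lay between 18.4 and 18.8 and the 75th percentiles differed by no more than 1.07 times, so the values had been brought to a like distribution before they were deposited, and no further normalization was applied. The lowest value of any array was 3.41 and the highest 14284. Arrays carry no read depth; the number of arrays limits the precision, above all the 2 controls, and levels near the array medians lie close to background. No pair of arrays held identical values. Each sample is taken as a separate animal from its own number in the title, but nothing else says so; the p-values measure only the spread between these samples.

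Of 45101 probe sets, 64 array controls were left out. Among the other 45037, the platform annotation lists 1 gene symbol for 34945, several for 932 and none for 9160; 34741 of the single symbols were updated through their gene identifiers with the RefSeq gene list of the mouse assembly GRCm38.p6, which served only for names and for which genes neighbour each other. No gene was named from a probe set with several symbols. For each of the 18193 genes the probe set with the highest mean over all 10 arrays was used (9010 genes had more than 1), and genes with a mean at or under the 25th percentile (4.89 on the log2 scale, an intensity of 13.6 after removal of the pseudocount) were left out, which left 13644 genes. Values were taken as log2(intensity + 16), so the differences of dim genes are understated.

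Comparisons were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with the number range and the letter as covariates and Benjamini-Hochberg adjustment over all genes tested at 0.05. Knockout versus control set the 8 knockouts against the 2 controls. Both controls lie in the lower number range, so with the range as a covariate the difference rested on the 3 knockouts and 2 controls there. The 5 knockouts of the upper range informed only the term of the letter and the spread. H versus L and M versus F came from a fit of all 10 arrays in 3 groups that share 1 estimate of the spread. Log2 differences and folds are estimates adjusted for the covariates on the log2(intensity + 16) scale, so that they can differ from the ratio of the group means, which are plain means ± SD of the intensities. Gene lists with at least 5 genes tested (41 of the 44 fixed ones) were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists; the estimated correlation and the rotation test fry were alternatives. Data were read with the R package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9. The tests, the covariates, the lists, the rule for named genes and all but 4 of the alternative settings were chosen before the data were examined; 14 lists of intestinal cell types and functions and 4 settings (no pseudocount, lung transcripts or smooth muscle transcripts as a covariate, and the 2 arrays highest in lung transcripts left out) were added after the tissue markers had been seen.

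Named in each comparison were Cftr, up to 12 genes of each direction with the largest differences among those past the threshold (with fewer than 6 past it, the 6 highest and 6 lowest by moderated t), the 4 members with the smallest p of each list past the threshold, at most 2 members of other lists, Sftpc, Scgb1a1, Fabp2 and Vil1 as tissue check, and Xist and Y chromosome genes as check of the letter. For M versus F the rule took 99 genes, of which 80, all members of lists past the threshold with the preset correlation, were left out after their values had been seen, to keep that comparison to the check of the letter. Members of the added lists were picked in the same way, except for 4 stem cell markers named after their values were seen, and the test of gene symbol families was added after the calls were seen.

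The fits were tested on simulated data, 5 data sets per comparison over the 13644 genes with 200 changed genes. The simulated noise was normal and independent between genes, with no effect of the number range. The shares below therefore need not hold for the real arrays, where genes vary together. For knockout versus control 52.2% of genes changed by 0.5 on the log2 scale were recovered, 87.3% of those changed by 1 and 99.1% of those changed by 2, with 3.88% false calls. For H versus L the shares were 53.6%, 85.0% and 97.1% with 4.61% false calls, and for M versus F 50.1%, 86.1% and 98.4% with 6.48% false calls. The alternatives covered the covariates, the number range, normalization between arrays, the filter, the choice among a gene's probe sets, variance moderation, array weights, the pseudocount, the split of the knockouts, each array left out in turn, and the test of the gene lists.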

Results

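The data were expression arrays of 8 cystic fibrosis knockout mice and 2 controls, F2 animals of a C57BL/6 by BALB/c cross. The knockouts carried the codes H (5 samples) or L (3 samples), and the letter M or F stood in every code. The labels name whole right lung as the source of the RNA and the series title an intestinal phenotype, so marker transcripts of several tissues were examined first.

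Transcripts of small intestine epithelium were among the brightest on every array. Lgals4, a galectin of intestinal epithelium, reached a mean intensity of 6919 over the 10 arrays, and Fabp2, the intestinal fatty acid binding protein, 4679. Fabp6, the bile acid binding protein of the ileum, averaged 4133 and Vil1, the microvillus protein villin, 2869. Of the 14 genes measured on the small intestine list, 11 lay in the top 5% of genes by mean intensity, and the median gene lay at the 99.2 percentile. Lung epithelium was also represented, at lower ranks. The median genes of the alveolar type 2, alveolar type 1 and club cell lists lay at percentiles 82.0, 70.1 and 84.9. In the top 5% lay 3 of 13, 0 of 11 and 2 of 9 of their genes. Among the 3 alveolar type 2 genes was Lyz1 (8128), which also stands on the Paneth cell list added later, so it does not speak for lung alone. The median gene of the lung endothelium list lay at percentile 52.1. Sftpc, surfactant protein C of alveolar type 2 cells, averaged 1972 and ranged from 1099 to 4169. Scgb1a1, the secretoglobin of airway club cells, averaged 3309 and ranged from 2011 to 5610. The ciliated cell factor Foxj1 (17.1) and the liver product Alb (13.6) stood near the array medians of 18.4 to 18.8. The 2 arrays highest in lung transcripts were knockout H replicate 2 and knockout H replicate 5, with mean log2 deviations of 0.70 and 0.45 over the lung epithelium lists.

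**Figure D1:**
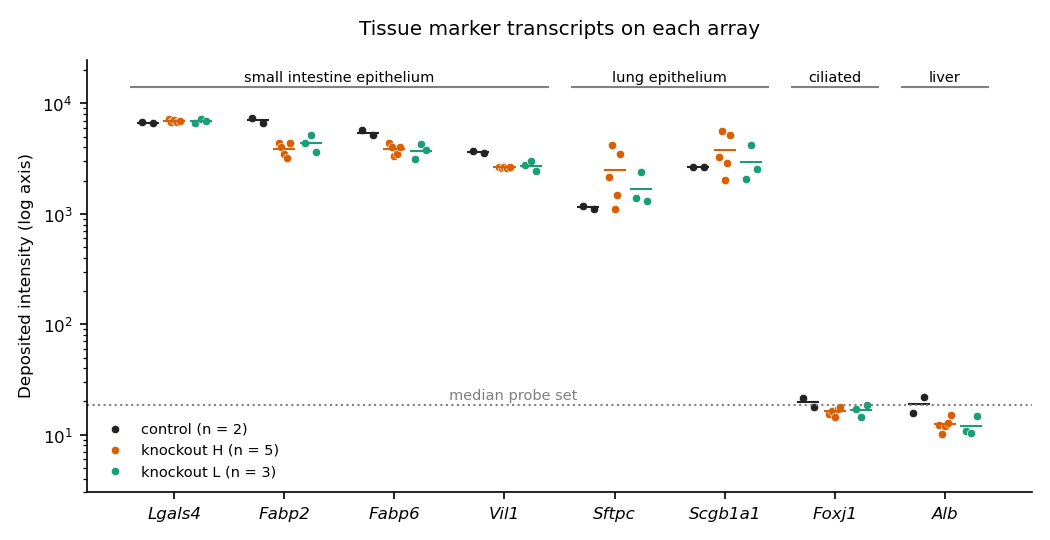
Deposited intensity (log axis) of marker genes of small intestine epithelium, lung epithelium, ciliated cells and liver on each of the 10 arrays; points are arrays, horizontal bars are group means and the dotted line is the median probe set. The small intestine and lung markers shown lie above 1000 on every array, while Foxj1 and Alb average 17.1 and 13.6. The lung markers shown are bright ones: the median genes of the alveolar type 2, alveolar type 1 and club cell lists had 192, 92.3 and 236.

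Knockout versus control addressed the effect of losing Cftr. Through the covariate for the number range its log2 differences rested on the lower range, with 3 knockouts and 2 controls. The group means cover all 8 knockouts. Cftr, the epithelial chloride and bicarbonate channel, was lower in all 8 knockouts (intensity 28.1 ± 6.63, SD, n = 8) than in both controls (134 ± 4.47, n = 2), a log2 difference of -1.91 ± 0.16 (SE; limma adjusted p = 0.00528). Lists of nutrient uptake and of lipid and drug metabolism of the enterocyte had lower medians in the knockouts, and lists of goblet, Paneth and crypt cells and of epithelial defence higher ones. These were among 14 lists written after the tissue markers were seen, of which 9 passed with camera and 0 with an estimated correlation (smallest adjusted p = 0.0717 with an estimated correlation). The lists of mucous and goblet cells and of xenobiotic metabolism fixed beforehand did not pass with camera. In all, 588 of 13644 genes passed the threshold, 381 lower and 207 higher. More than 2-fold changes were seen for 75 lower and 27 higher genes, and the median difference over all genes was -0.0047. A second Cftr probe set read 5.41 in knockouts and 6.31 in controls, below the level kept for testing, and says nothing on the knockout. Which part of the transcript either probe set covers was not given in the sources used here.

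Among the genes that fell most, Pdzk1, a scaffold for transporters of the brush border, was 98.4 ± 57.8 in knockouts and 1121 ± 483 in controls (log2 difference -3.50 ± 0.57, limma adjusted p = 0.017). Cyp3a25, a drug-metabolizing cytochrome P450, fell by 3.23 on the log2 scale, and Cubn, the ileal receptor for cobalamin with intrinsic factor, fell by 2.60. Serpina1b, an alpha-1-antitrypsin, and the fatty acid hydroxylase Cyp4v3 had log2 differences of -2.51 and -2.42. Those of Rdh7, a retinol dehydrogenase, the mitochondrial carrier Slc25a48 and the mitochondrial arginase Arg2 were -2.39, -2.35 and -2.34. The coiled-coil gene ccdc198, the membrane protein Susd2 and Slc6a20a, an imino acid transporter, followed with -2.27, -2.19 and -1.96. For each of these 11 genes, all 8 knockouts lay below both controls.

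Retnlb, a resistin-like protein secreted by goblet cells, rose most, from 266 ± 347 in the 2 controls to 3384 ± 2158 in the 8 knockouts. Its log2 difference was 5.02 ± 1.18 (limma adjusted p = 0.0485), and 7 of 8 knockouts exceeded both controls. The call of Retnlb was lost in 16 of 29 alternative settings, among them those that left out any 1 array other than knockout H replicates 2 and 3 (largest adjusted p 0.41 in limma, log2 difference 3.37 to 6.41). Pla2g2a, the secreted phospholipase of Paneth cells, whose gene is disrupted in C57BL/6 mice, was 4.16-fold higher (8287 ± 1277 against 1996 ± 64.7, limma adjusted p = 0.00528). The disrupted allele can segregate in this F2 cross and the genotypes at Pla2g2a are not given. With 2 controls, an uneven share of that allele cannot be told apart from the knockout. The neutrophil glycoprotein gene Cd177 rose 4.08-fold and Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, 3.91-fold. The water channel Aqp4 rose 3.71-fold and the secreted glycoprotein Lrg1 3.68-fold. The transcription factor Mecom rose 2.85-fold, the complement protease Cfi 2.79-fold and Prom1, a membrane protein of crypt cells, 2.75-fold. The neuropeptide Vip rose 2.69-fold, Car8, a carbonic anhydrase relative without activity, 2.69-fold, and Ero1a, an oxidase of protein folding, 2.65-fold. All 8 knockouts lay above both controls for each of these except Lrg1, for which 7 did.

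**Figure D2:**
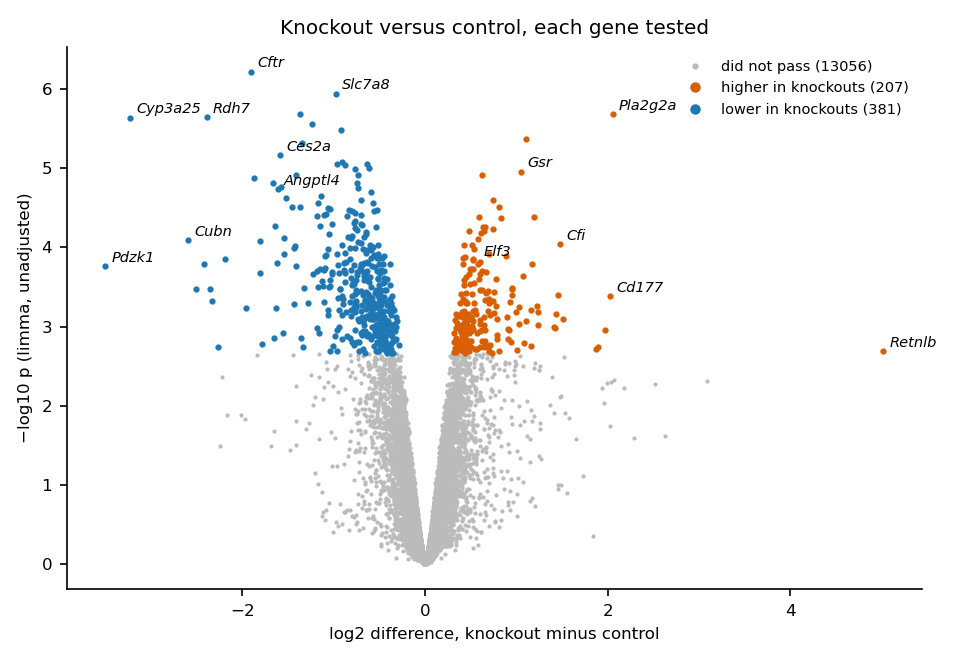
Log2 difference (knockout minus control, horizontal) against unadjusted p from limma (negative log10, vertical) for each of 13644 genes tested; coloured points passed an adjusted p of 0.05, 207 higher and 381 lower. Retnlb lies farthest right at 5.02 and Pdzk1 farthest left at -3.50.

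Of the 41 fixed gene lists tested, 7 passed with camera at the preset correlation. All 7 calls were lost with an estimated correlation, and fry called 0 of 41 (smallest adjusted p 0.134). The small intestine epithelium list was lower (median log2 difference -0.53, camera adjusted p = 0.0052; adjusted p = 0.954 with an estimated correlation). Past the threshold were 3 of its 14 genes, all lower: the intestinal transcription factor Cdx2 (-0.85), Fabp2 (-0.93) and Vil1 (-0.51). Adjusted over the list alone, 8 members were lower and 1 higher. The sodium-glucose transporter Slc5a1, at -0.55, did not pass over all genes (limma adjusted p = 0.0716). Hypoxia response genes had higher values for 16 of 17 members (median 0.39, camera adjusted p = 0.000575). Cell cycle genes had higher values for 22 of 24 (median 0.27, camera adjusted p = 0.000587), heat shock genes for 14 of 15 (median 0.45, 0.00354) and collagen and matrix genes for 19 of 22 (median 0.20, 0.0103). Each of these 4 lists had an adjusted p = 0.954 with an estimated correlation. No single member of these 4 lists passed over all genes, and adjusted over the list alone only 3 cell cycle genes did. The mean deviations of these 4 lists, not adjusted for covariates, overlapped between knockouts and controls. On the collagen and matrix list control replicate 2 (-0.02) lay above knockout H replicates 1, 2 and 5 and L replicate 2 (-0.26, -0.03, -0.04 and -0.21). The knockouts highest there, H replicate 3 and L replicates 1 and 3 (0.20, 0.22 and 0.24), were also the highest in smooth muscle genes (0.45, 0.26 and 0.35). Control replicate 2 (-0.19) lay above knockout H replicate 2 (-0.33) on the hypoxia list and, at -0.27, above knockout H replicate 3 (-0.40) on the heat shock list. On the cell cycle list control replicate 1 (-0.18) lay above knockout H replicate 3 (-0.29). Egln3, an oxygen-sensing hydroxylase, differed by 1.99 and the glucose transporter Slc2a1 by 1.26. The collagen hydroxylase P4ha1 differed by 0.87 and the glycolytic enzyme Pgk1 by 0.53. The replication genes Pcna, Mcm6 and Mcm2 differed by 0.55, 0.38 and 0.33 and the cyclin Ccna2 by 0.56. The chaperones Hsp90aa1, Hspd1, Hspe1 and Hspa4 differed by 0.70, 0.53, 0.45 and 0.28. The matrix genes Fn1, Col5a2, Mmp14 and Mfap5 differed by 1.15, 0.71, 0.41 and 0.22.

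Antigen presentation genes had lower values for 14 of 14 members (median -0.61, camera adjusted p = 0.0273; adjusted p = 0.954 with an estimated correlation). None passed in limma over all genes, and none adjusted over the list alone. The peptide loading genes Tapbp and Tap2 differed by -0.48 and -0.60, the class II gene H2-DMa by -0.86 and its regulator Ciita by -0.30. Interferon response genes had lower values for 20 of 22 members (median -0.35, camera adjusted p = 0.0273; adjusted p = 0.954 with an estimated correlation). The interferon regulator Irf7 fell 1.88-fold (limma adjusted p = 0.0401), and 2 members were lower adjusted over the list alone. The call of Irf7, the 1 member past the threshold over all genes, was lost in 12 of 29 alternative settings, among them the lower number range alone and 6 that left out an array (knockout L replicates 1 and 2, knockout H replicates 3 and 5 and either control). The antiviral genes Rsad2, Oasl2 and Xaf1 differed by -1.24, -1.28 and -0.49 without passing over all genes. Mean deviations of the antigen presentation list were 0.49 and 0.29 in the controls, and knockout L replicate 2 (0.81) and knockout H replicate 2 (0.60) lay above both. The natural killer cell list stood at 0.36 and 0.33 in the controls, 0.73 and 0.62 in these 2 knockouts and -0.87 and -0.55 in knockout H replicates 1 and 3, where antigen presentation stood at -0.94 and -0.62. The T cell list was likewise highest in these 2 knockouts (0.45 and 0.33, controls 0.19 and 0.16), and on the interferon response list knockout L replicate 2 (0.57) also exceeded both controls (0.40 and 0.26). The natural killer and T cell lists did not pass (median -0.57 and -0.20, camera adjusted p = 0.549 and 0.185). The calls of antigen presentation and interferon response were lost without covariates, without knockout H replicate 4 and without control replicate 2, and that of antigen presentation also without knockout L replicate 3. The call of collagen and matrix was lost without covariates, control replicate 1 or knockout L replicate 3, and that of heat shock without control replicate 1.

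Single members of lists that did not pass also changed. Slc9a3r1, a scaffold that binds CFTR, fell (-0.74), as did Angptl4, an inhibitor of lipoprotein lipase (-1.62), the clock gene Per1 (-0.70) and the stress gene Trib3 (-0.38). Gsr, glutathione reductase, rose (1.05), as did the growth factor binding protein Igfbp2 (0.75) and the matrix genes Lum (0.95) and Ccn2 (0.64). So did the mannose receptor Mrc1 (0.48) and Agr2, a protein of mucin folding (0.65). Of 17 genes tested near Cftr on its chromosome, the sulfate transporter Slc13a1 fell (-1.06) and Tspan12 rose (0.48), and the list as a whole did not pass (median -0.04, camera adjusted p = 0.811). The strain alleles around Cftr are not given. For its neighbours, alleles inherited together with the disrupted gene cannot be told apart from the loss of Cftr. Lung transcripts varied without passing. Sftpc was 2178 ± 1107 in the 8 knockouts and 1149 ± 58.3 in the 2 controls (limma adjusted p = 0.509). Scgb1a1 was 3467 ± 1379 and 2676 ± 11.8 (0.757), and the alveolar type 2 list had a median of 0.30 (camera adjusted p = 0.623). The smooth muscle list did not pass (median -0.12, camera adjusted p = 0.936), though its mean deviation separated control replicate 2 (0.64) from control replicate 1 (-0.48). The genes that check the letter did not pass here, with log2 differences of -0.49 for Xist, 0.06 for Eif2s3y, 0.10 for Kdm5d and 0.16 for Uty.

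Of 14 lists of intestinal cell types and functions, written after the tissue markers were seen, 9 passed with camera and 8 with fry. Their p-values were adjusted over these 14 lists, apart from the 41 fixed ones. None passed with an estimated correlation. Brush border peptidases and disaccharidases were lower for 14 of 15 genes (median -0.82, camera adjusted p = 3.56e-09; adjusted p = 0.0717 with an estimated correlation). The 6 past the threshold included the aminopeptidases Xpnpep2 (-1.81) and Anpep (-1.23), trehalase, Treh (-1.80), and the peptidase Naaladl1 (-0.90). Genes on the list named apical nutrient transporters were lower for 16 of 18 (median -0.56, camera adjusted p = 2.03e-06, and 0.104 with an estimated correlation). The 5 past the threshold included the neutral amino acid transporters Slc6a19 (-1.56) and Slc7a8 (-0.98) and the fructose transporter Slc2a5 (-0.95). Standing on this list does not place a transporter such as Slc7a8 on the apical side. Lipid absorption genes were lower for 14 of 18 (median -0.52, 5.99e-06; adjusted p = 0.082 with an estimated correlation). The triglyceride synthesis genes Dgat1 (-0.97) and Mogat2 (-0.75) fell, while the sterol importer Npc1l1 (-1.17) did not pass. Drug-metabolizing enzymes and efflux pumps were lower for 19 of 23 (median -0.73, 3.56e-09; adjusted p = 0.082 with an estimated correlation). The 9 past the threshold included the carboxylesterases Ces2a (-1.58) and Ces2e (-0.74) and the efflux pump Abcc2 (-1.37). The xenobiotic metabolism list fixed beforehand did not pass (median -0.04 over 11 genes, camera adjusted p = 0.549). Genes of the distal small intestine were lower for 6 of 7 (median -0.54, 0.00544; adjusted p = 0.104 with an estimated correlation). The bile acid exporter Slc51a (-0.69) and the peptide hormone Nts (-0.83) fell, while Fabp6 (-0.54) did not pass. The call of the distal list was lost without control replicate 1.

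Goblet cell genes were higher for 13 of 16 (median 0.58, camera adjusted p = 0.000344; adjusted p = 0.303 with an estimated correlation). Besides Retnlb and Agr2, the mucin glycosylation enzyme Galnt12 rose (0.64), while the secretory lineage factor Atoh1 (0.999) did not pass. Knockout H replicate 2 (-0.43) lay below control replicate 2 (-0.38) in the mean deviation of the list. The mucous and goblet cell list fixed beforehand did not pass (median 0.08 over 13 genes, camera adjusted p = 0.185). Paneth cell genes were higher for 8 of 10 (median 0.59, 0.000344; adjusted p = 0.0717 with an estimated correlation). Pla2g2a passed over all genes and 5 members were higher adjusted over the list alone. Mmp7, which activates defensins, Sox9, a transcription factor, and Reg3g, an antibacterial lectin, differed by 1.26, 0.63 and 0.30. Crypt base genes were higher for 10 of 16 (median 0.20, 0.00544; adjusted p = 0.104 with an estimated correlation). Prom1, the adhesion receptor Cd44 (1.08) and Olfm4 (0.92) rose, while the growth factor regulator Lrig1 (0.39) did not pass. The stem cell markers Lgr5 (-0.42), Axin2 (-0.42), Smoc2 (-0.13) and Ascl2 (-0.09), singled out after their values were seen, had lower values without passing. Epithelial defence genes were higher for 11 of 16 (median 0.35, 0.00313; adjusted p = 0.0717 with an estimated correlation). Retnlb, Duoxa2 and the NF-kappaB pathway genes Nfkbiz (0.95) and Tifa (1.16) rose. The pan-epithelial list did not pass (median 0.02, camera adjusted p = 0.623), although its member Elf3, an epithelial transcription factor, rose (0.58).

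**Figure D3:**
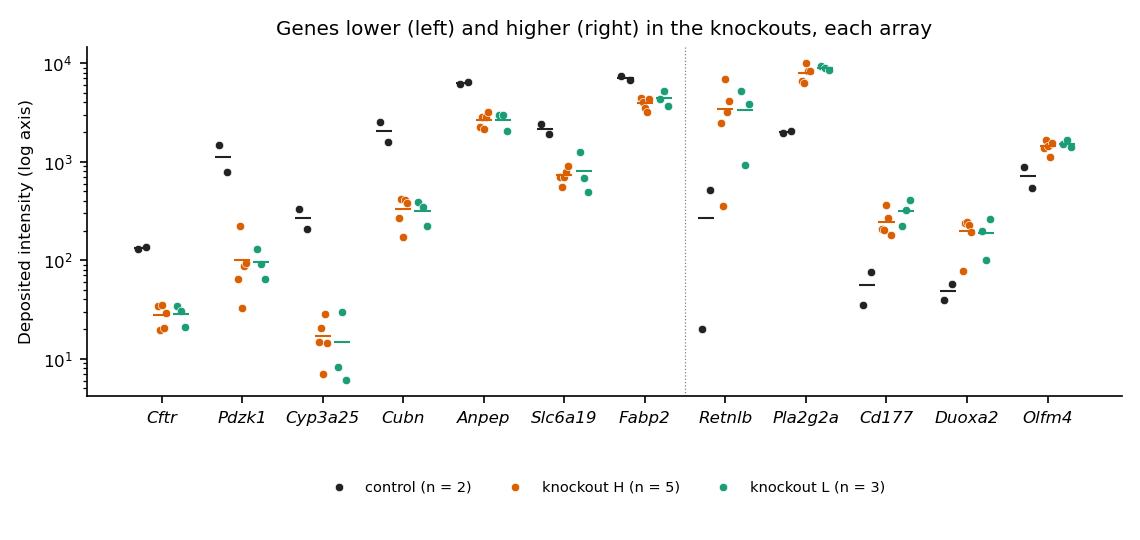
Deposited intensity (log axis) of Cftr and of 6 further genes lower and 5 higher in the knockouts, on each array; points are arrays and horizontal bars group means for the controls (n = 2), knockouts H (n = 5) and knockouts L (n = 3). Cftr lies at 19.7 to 35.4 in the knockouts and at 131 and 137 in the controls.

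**Figure D4:**
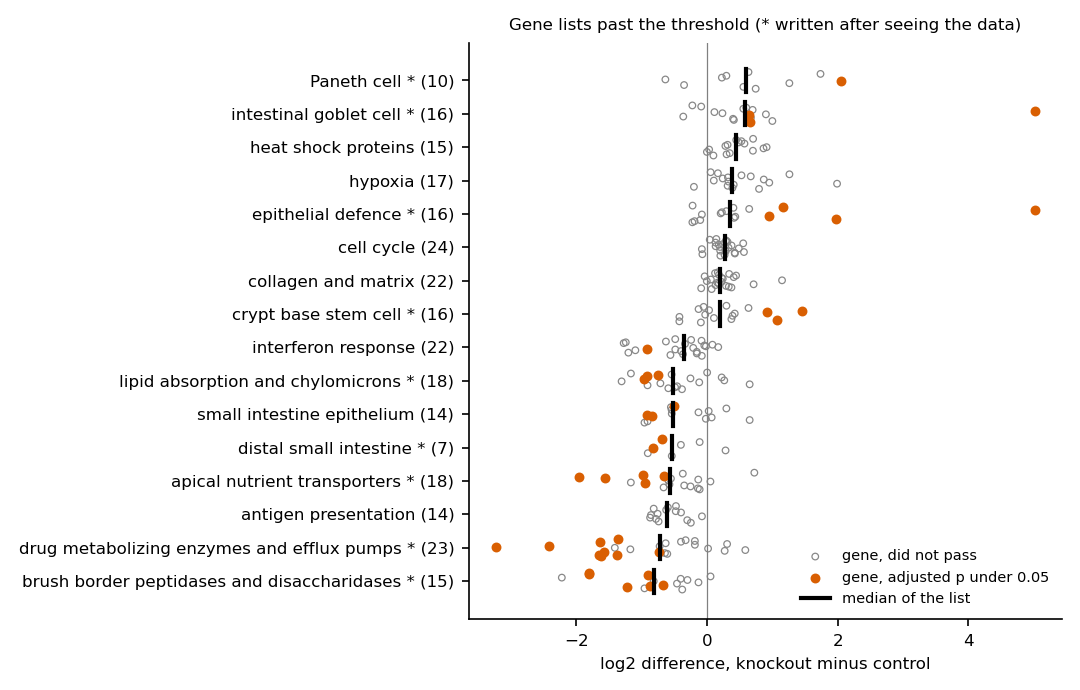
Log2 difference (knockout minus control) of each gene tested on the lists past the camera threshold, with list sizes in brackets; filled points passed over all genes, vertical bars are list medians, and asterisks mark lists written after the tissue markers were seen. Medians run from -0.82 for brush border peptidases to 0.59 for Paneth cells.

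The knockout calls rested on the 2 controls: limma called 0 genes without control replicate 1 (1783 at an unadjusted p under 0.05), 57 without control replicate 2, 121 without knockout H replicate 4, 191 without knockout L replicate 3 and 263 without knockout H replicate 5, although all 60 named genes that passed kept their direction in each of these fits. Lrg1, ccdc198 and Ccn2 lost their calls in 16 of 29 alternative settings, like Retnlb, and Agr2 and Nts in 15; over the 60 genes the number of such losses ran from 1 to 16. Within the lower number range, which holds both controls and 3 knockouts, 1033 genes passed, 514 of them among the 588. That fit is no independent check, since the main difference rested on the same 5 arrays. Without covariates 1366 passed, 535 of them among the 588.

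Knockout H versus knockout L set the letters apart within the knockouts, under a series title that speaks of weight. No gene passed in limma (0 of 13644, with 303 at an unadjusted p under 0.05 and a smallest adjusted p of 1.0). The genes with the highest moderated t, none of them past the threshold, were the tight junction gene Cldn8 (log2 difference 0.67, all 5 H above all 3 L samples), Ces2a (0.40), the kinase Map3k6 (0.39), Plekhm3 (0.29), Clca3b (0.43) and Pyroxd2 (0.82). Those with the lowest were Smc5, of DNA repair (-0.29), Tesc (-0.40), Ccdc181 (-0.28), Mga (-0.37), the centrin Cetn2 (-0.28) and 4930526I15Rik (-0.56). Cftr was 27.8 ± 7.29 in H (n = 5) and 28.7 ± 6.84 in L (n = 3). The tissue markers differed by 0.39 (Sftpc), 0.35 (Scgb1a1), -0.17 (Fabp2) and -0.01 (Vil1), none past the threshold. The same held for Xist (-0.34), Eif2s3y (-0.02), Kdm5d (0.0010) and Uty (0.05).

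Of 41 fixed lists 8 passed with camera at the preset correlation, none with an estimated correlation or with fry, and none of the 14 added lists passed. No member of any of the 8 lists passed, over all genes or adjusted over the list alone, and on none of the 8 did the mean deviations, not adjusted for covariates, set all H arrays apart from all L arrays. Cholesterol and fatty acid synthesis genes were lower in H for 20 of 20 members (median -0.27, camera adjusted p = 1.06e-08; adjusted p = 0.748 with an estimated correlation). The members with the smallest p were the sterol synthesis enzymes Idi1 (-0.45), Msmo1 (-0.39) and Dhcr7 (-0.38) and the sterol sensor Insig1 (-0.25). Smooth muscle genes were lower for 11 of 11 (median -0.49, 1.87e-06; adjusted p = 0.748 with an estimated correlation), led by the muscle genes Actg2 (-0.79), Des (-0.72), Cnn1 (-0.64) and Lmod1 (-0.34). Knockout H replicate 3 (0.45) lay above all 3 L arrays on this list (0.26, -0.22 and 0.35), and L replicate 2 (-0.22) lay among the other H arrays (-0.46 to -0.12). B and plasma cell genes were higher for 10 of 10 (median 0.24, 0.000396; adjusted p = 0.748 with an estimated correlation), led by the immunoglobulin gene Ighm (0.66) and the B cell genes Cd22 (0.32), Cd79b (0.29) and Blk (0.16). On this list H replicates 2 and 4 (0.31 and 0.35) lay above the L arrays (-0.31, -0.01 and 0.02), while H replicates 1, 3 and 5 (-0.33, -0.32 and -0.09) lay below at least 2 of the 3. Lower medians were also seen for circadian clock (-0.16, 0.00266), collagen and matrix (-0.21, 0.00702), hypoxia (-0.20, 0.00902), interferon response (-0.15, 0.0225) and skeletal muscle genes (-0.11, 0.0397). Each of these 5 lists had an adjusted p = 0.748 with an estimated correlation. The members with the smallest p were the clock genes Per3 (-0.55), Cry1 (-0.39), Cry2 (-0.31) and Ciart (-0.22) and the matrix genes Postn and Fn1 (both -0.58), Tnc (-0.48) and Serpinh1 (-0.39). Next were the glycolytic genes Pfkl (-0.45), Aldoa (-0.20) and Tpi1 (-0.14) with P4ha1 (-0.37). Of the last pair of lists these were the interferon-induced Ifit3 (-0.38), Oasl1 (-0.29), Bst2 (-0.23) and Stat2 (-0.20), and the muscle genes Acta1 (-0.46), Ckm (-0.38), Pvalb (-0.12) and Tnni2 (-0.09). Within the lower number range, where 2 H arrays and a lone L array lie, the L array being assumed to vary like the other groups, 25 genes passed in limma, while within the upper range the count was 0 (210 at an unadjusted p under 0.05). B and plasma cell and smooth muscle genes passed in each of the 10 fits that left out an array, cholesterol and circadian genes in all but that without knockout L replicate 1, and the other lists lost their calls in 3 to 6 of them. The interferon response list turned to higher in H without knockout H replicate 4, where it did not pass. Without covariates 3 of the 8 lists kept their calls, and B and plasma cell, circadian clock, collagen, hypoxia and skeletal muscle genes lost them.

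Letter M versus letter F checked the titles' codes. Xist, the transcript of the inactive X chromosome, was 8.31 ± 5.33 in 6 arrays of letter M and 1059 ± 337 in 4 of letter F (log2 difference -5.35 ± 0.21, limma adjusted p = 7.88e-05). The Y chromosome genes Eif2s3y (106 ± 18.0 against 4.24 ± 0.462) and Kdm5d (56.9 ± 6.06 against 4.53 ± 0.473) were higher in M by 2.64 and 1.80 on the log2 scale (limma adjusted p = 0.000332 and 0.000196). Uty, also on the Y chromosome, was 33.3 ± 6.35 against 9.90 ± 0.315 (0.84, limma adjusted p = 0.132). For these 4 genes all 10 arrays lay on the side of their letter. Xist, Eif2s3y and Kdm5d were the 3 genes past the threshold (659 at an unadjusted p under 0.05). X-linked Eif2s3x (-0.55), Kdm6a (-0.57) and Kdm5c (-0.26), genes that escape X inactivation, and Pbdc1 (-0.47) had lower values in M without passing. Further genes with extreme moderated t were Wdr82 (0.92), Cep63 (0.50) and Pik3r4 (0.48), higher in M, and Cd22 (-0.64), Cldn8 (-0.48) and Slc25a13 (-0.45), lower, and none passed. Cftr (0.16), Sftpc (0.11), Scgb1a1 (-0.06), Fabp2 (0.02) and Vil1 (-0.05) did not pass either. Within the lower and the upper number range, 4 and 2 genes passed, 3 and 1 of them among these 3; the upper range holds a lone array of letter F, assumed to vary like those of letter M.

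Of 41 fixed lists 22 passed with camera between the letters, none with an estimated correlation and only the X escape list with fry (median -0.55, camera adjusted p = 1.0e-08; adjusted p = 0.0542 with an estimated correlation). B and plasma cell genes were lower in M for 10 of 10 members (median -0.46, camera adjusted p = 2.42e-06; adjusted p = 0.549 with an estimated correlation), with 5 lower adjusted over the list alone. Knockout H replicate 2, of letter M, lay among the F arrays on this list (0.31, F arrays -0.01 to 0.43). Smooth muscle genes were higher for 11 of 11 (median 0.53, 4.54e-06; adjusted p = 0.667 with an estimated correlation). That call was lost without either control, and the mean deviations, not adjusted for covariates, overlapped: M arrays ran from -0.46 to 0.64, highest in control replicate 2, and F arrays from -0.48, in control replicate 1, to 0.35. Only the X escape, B and plasma cell and circadian clock lists passed in each of the 10 fits that left out an array, and the other 19 lists lost their calls in 1 to 6 of them. Lower medians in M were also found for cell cycle (-0.19), interferon response (-0.25), antigen presentation (-0.47), T cell (-0.19) and ribosomal protein genes (-0.09). Higher medians were found for cholesterol synthesis (0.17), circadian clock (0.27), heart muscle (0.29), glucocorticoid response (0.18), collagen (0.14), hypoxia (0.16) and fibroblast genes (0.16). The same held for unfolded protein response (0.09), immediate early (0.10), heat shock (0.10), airway ion channel (0.07), lung endothelium (0.10) and mast cell genes (0.06) and for the neighbours of Cftr (0.07). Over the 22 lists the estimated correlation gave adjusted p-values from 0.0542 to 0.702, and 10 lists passed without covariates. Without passing there, interferon response genes turned to higher in M without knockout L replicate 1 and immediate early genes to lower in M without covariates.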

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

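The tests of the correlation among lung genes, of the other splits of the knockouts into H and L and of chance position on chromosome 9 were chosen after the result was seen; the other tests of this part were chosen before it, on lists of which the intestinal ones were written after the tissue markers were seen.

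Of 150 values of named genes tested within the 5 samples of group H, 12 had 1 sample far from the other 4 by Dixon's test, which by chance picks out about 1 in 20 groups (7.5 expected). Knockout H replicate 4, the one sample of letter F in this group, stood apart for Xist (713.2, the others 5.73 to 6.528), Kdm5d (5.104, the others 52.87 to 63.87) and Eif2s3x (943.4, the others 512.3 to 569.8). It also stood apart for Blk (17.97, the others 11.78 to 13.29), Cd22 (63.92, the others 29.96 to 37.66) and Smc5 (26.18, the others 33.98 to 36). Knockout H replicate 3 stood apart for Lum (309.6, the others 188.7 to 219.4), Per3 (40.9, the others 18.91 to 22.52) and Pyroxd2 (74.47, the others 41.7 to 45.16). The same sample did so for Tnc (216.3, the others 98.71 to 125.1) and Xaf1 (49.05, the others 72.01 to 80.06). In knockout H replicate 2, ccdc198 was 69.48, with the others at 12.15 to 20.31.

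Lung and small intestine transcripts stood side by side on every array, under a label that names lung. The 25 lung epithelium genes above the median intensity rose and fell together (median pairwise correlation 0.570, against a 95th percentile of 0.0713 in 1000 matched random lists, and 0.654 for the 23 on no intestinal list), as RNA of lung admixed in varying amount could give. Cross-hybridisation of lung probe sets with intestinal transcripts would tie the lung mean to the intestinal mean, but their correlation was -0.168 (95% interval -0.72 to 0.52, permutation p = 0.651, n = 10) and 0.267 without knockout H replicates 2 and 5. That value met the bound set beforehand against it, a correlation at or under 0, but its interval does not exclude a positive one, so after the value was seen this explanation was left open. No biological explanation was tested, and the design gives none for transcripts of both organs in the same sample.

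Brush border, transporter and lipid absorption lists were lower in the knockouts with camera (6 of 15, 5 of 18 and 3 of 18 members past the threshold in limma), but not with an estimated correlation (adjusted p = 0.0717, 0.104 and 0.082). A varying share of lung RNA was argued against: with lung transcripts as a covariate the 381 lower genes kept 101% of their median (-0.65 before, -0.66 after, interquartile range 0.40), and 380 still passed. A lower share of epithelium was argued against, for the genes listed, by the pan-epithelial list. Its median was 0.021 (95% interval -0.14 to 0.17) where brush border and transporter genes had -0.59 (-0.87 to -0.38). These intervals, and those of the position lists that follow, come from resampling the genes of a list. They treat the genes as independent and hold no spread between animals, so the argument does not cover that spread. Another position of the sampled intestine could not be told apart from an effect of the knockout: the distal list had a median of -0.54 and the proximal list -0.08, apart by 0.46 (95% interval -0.02 to 0.96), short of the 0.5 set beforehand, and both medians were negative, which met the bound set beforehand against it, but the interval of the proximal median (-0.23 to 0.31) does not exclude a positive one. The proximal genes Gata4, Lct, Cybrd1 and Gip averaged only 14.3, 15.1, 18.6 and 21.8, where the pseudocount understates differences. The other proximal genes tested averaged 73.2 or more, and the dimmest distal gene tested, Hoxb6, 88.1. The proximal median can thus lie nearer 0 through dim genes. The loss of Cftr, which the design names, stays open beside another position as a hypothesis.

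Of the genes with an unadjusted p under 0.01 between the letters, 7 lay within 100 neighbouring genes on chromosome 9 (Cep63, Ryk, Pik3r4, Wdr82, Acy1, Parp3 and Tmem115), a region singled out after the values were seen. Chance position of independent genes was argued against, since a share of 0.006 of 1000 shuffles of gene positions gave a window of as many. The shuffles treat neighbouring genes as independent. Of 100 drawn splits of the 10 arrays into 6 and 4, the real one among them, 21 gave as many or more (median 5, highest other 19). Such a window is thus not unusual among groupings of these arrays. That met the share set beforehand for a haplotype of the F2 cross that fell unevenly on the letters. The splits counted windows on any autosome and hold no genotypes, however, so they do not test for a haplotype. An effect of sex, with which the letters went on all 10 arrays by Xist and the Y chromosome genes, stays open and untested.

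For the calls themselves, 1 of the 45 splits of the 10 arrays into 2 and 8, the real one, gave as many genes as 588. The highest other gave 55, with knockout L replicate 2 and knockout H replicate 2 set as controls. That met the bound set beforehand against chance, a share under 0.05. The splits exchange arrays between the number ranges, however, while both controls lie in the lower one. The 10 splits of the controls' own range into 2 and 3 are too few for a share under 0.05, so chance was not excluded. Without control replicate 1 limma called 0 genes (1783 at an unadjusted p under 0.05). Of the 55 splits of the 8 knockouts into 5 and 3 that could be fitted (1 could not), 55 gave at least the real count of 0 in limma (303 genes at an unadjusted p under 0.05), as every split must, so this comparison says nothing on chance. The highest other gave 137 genes, with knockout L replicate 1 and knockout H replicates 1 and 3 set apart, and 7 splits gave any. Whether such a count reflects a structure among the knockouts was not tested. Between the letters 2 of 100 splits drawn from 210 gave at least the real 3 genes, the real split and another that gave 18. The share lay under the 0.05 set beforehand against chance. As the other split gave more genes than the real one, the count alone does not exclude chance. For the 3 real genes, Xist, Eif2s3y and Kdm5d, all 10 arrays lay on the side of their letter.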

How the results depend on the processing

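The settings without a pseudocount, with lung or smooth muscle transcripts as a covariate and without the 2 arrays highest in lung transcripts were chosen after the data were seen, as were the 14 added lists. All 60 named genes past the threshold between knockouts and controls kept their direction wherever they were tested, though no call was kept without control replicate 1 and 11 without control replicate 2. Where a control was left out, the lone one was assumed to vary like the other groups, as were the lone L array of the lower number range and the lone F array of the upper one. Sizes moved by over 1.5 times for 14 of these 60 genes with a pseudocount of 64, for 6 with the mean of probe sets and for fewer in other settings. Over the settings the log2 difference of Mecom ran from 0.55 to 1.84 and that of Car8 from 0.57 to 1.63. Array signal near background limits dim genes, and unless stated the cause was not tested.

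Against 588 genes between knockouts and controls, limma called 1366 without covariates, 1222 with the letter alone, 1033 in the lower number range, 968 with array weights, 951 with lung transcripts as a covariate and 349 with the knockouts split into H and L. It called 408 without the 2 arrays highest in lung transcripts. With 1 array left out the counts ran from 0 (1783 at an unadjusted p under 0.05) to 813. Between H and L limma called 25 in the lower number range and otherwise 0 (303 at an unadjusted p under 0.05 with all arrays), also with each array left out. Between the letters it called 5 without covariates, 10 over all probe sets, 5 with the mean of probe sets and 5 with array weights, and 3 with each array left out. With an estimated correlation camera called 0 fixed and 0 added lists between knockouts and controls, 0 between H and L and 0 between the letters. Fry called 0 and 0 fixed lists in the first pair of comparisons and 1 between the letters, where camera called 10 without covariates. With 1 array left out camera called 6 to 9 fixed and 8 to 10 added lists between knockouts and controls, 4 to 17 between H and L and 14 to 23 between the letters.

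Of lists that had passed with camera, interferon response turned direction between H and L without knockout H replicate 4 and between the letters without knockout L replicate 1, and immediate early genes between the letters without covariates, each without passing there. Among named genes, signs reversed only for those that had not passed. Between knockouts and controls these were Xist (0.43), Eif2s3y (-0.38) and Kdm5d (-0.20) with the number range alone and Eif2s3y (-0.022) with the letter alone. Without the 2 arrays highest in lung transcripts Scgb1a1 was -0.23 and Ascl2 0.019, and with the mean of probe sets Smoc2 was 0.050 and Ascl2 0.032. With 1 array left out, Ascl2 ran from -0.256 to 0.0957, Scgb1a1 ran from -0.146 to 0.523, Eif2s3y from -0.00916 to 0.106 and Uty from -0.0172 to 0.373.

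Between H and L, Eif2s3y was 1.22 without covariates, 1.30 with the number range alone, 0.018 with the letter alone, 0.0688 in the lower range, 0.027 with a pseudocount of 1 and 0.046 with none. It was 0.018 with lung transcripts and 0.074 with smooth muscle transcripts as a covariate, 0.0013 without the 2 arrays and -0.119 to 0.0625 with 1 array left out. Kdm5d was -0.0064 with the letter alone, -0.11 in the upper range, -0.0024 after median centring, -0.0092 with array weights, -0.00732 with a pseudocount of 64, -0.036 in the 8 knockouts alone and -0.0471 to 0.105 with 1 array left out. Uty was -0.0641 in the upper range, -0.036 with the mean of probe sets, -0.0187 in the 8 knockouts alone and -0.0187 to 0.167 with 1 array left out. Vil1 was 0.13 in the lower range, 0.015 after quantile normalization, 0.0060 with array weights and -0.0971 to 0.020 with 1 array left out. Cftr was 0.0430 in the lower range, 0.0060 without the 2 arrays and -0.183 to 0.0123 with 1 array left out. Tpi1 was 0.013 in the lower range. In the upper range Tnni2 was 0.0952, Bst2 0.0535 and Xist 0.0605, and Tnni2 ran from -0.247 to 0.0242 with 1 array left out. Cd79b was -0.024 with the number range alone. Scgb1a1 was -0.20 with smooth muscle transcripts as a covariate and -0.0830 to 0.633 with 1 array left out, and Sftpc -0.00688 with lung and -0.38 with smooth muscle transcripts as a covariate.

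Between the letters, Vil1 was 0.00871 without covariates and -0.118 to 0.0202 with 1 array left out. Scgb1a1 was 0.42 in the lower range, 0.0592 with array weights, 0.50 with smooth muscle transcripts as a covariate and -0.475 to 0.375 with 1 array left out. Sftpc was -0.78 in the upper range, -0.47 without the 2 arrays and -0.397 to 0.531 with 1 array left out. Fabp2 was -0.24 in the upper range, -0.017 after quantile normalization, -0.19 without the 2 arrays and -0.183 to 0.167 with 1 array left out.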

Other observations

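The symbol families and the relation of Sftpc to Scgb1a1 were tested after the calls or the tissue markers were seen. Solute carriers made up 32 of the 381 genes lower in the knockouts, where 7.51 were expected from 269 tested (exact hypergeometric test, adjusted p = 7.14e-11 over 18 tests), and 2 of the genes higher. Of 39 cytochromes P450, 6 were lower (1.09 expected, adjusted p = 0.00613), as were 3 of 13 hydroxysteroid dehydrogenases (adjusted p = 0.023) and 2 of 5 UDP-glucuronosyltransferases (adjusted p = 0.0265). Carboxylesterases (2 of 11 lower, adjusted p = 0.109) and ATP-binding cassette genes (3 of 34 lower, adjusted p = 0.176) did not pass. Among the higher genes, translation initiation factors of the Eif family numbered 4 of 46 (0.698 expected, adjusted p = 0.023). The test counts genes as independent, which genes of the same cells are not.

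Sftpc and Scgb1a1, markers of different lung cells, rose and fell together over the 10 arrays (r = 0.939, permutation p = 0.00012, adjusted for 2 relations 0.00024; rank correlation 0.879). The correlation was 0.816 without knockout H replicates 2 and 5, and 0.978 and 0.974 within the lower and the upper number range. The number range itself went with 88 genes in limma beside the group and the letter, and with 45 within the 8 knockouts. Each letter holds 1 control, so whether the effect of the knockout differed between the letters could not be told. The first principal component, with 34.0% of the variance, set the controls (31.1 and 22.8) apart from the knockouts (-15.8 to -1.70), and correlations between arrays ran from 0.958 to 0.992. For the 60 named genes past the threshold between knockouts and controls, other probe sets above the level kept for testing differed in the same direction in 24 of 24 cases; this count does not cover named genes that did not pass, such as Smoc2 and Ascl2.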
